A study of Mus musculus with 8 samples.

How the data were processed

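RNA from the mandibular molar tooth germs of mouse embryos was measured on 8 Affymetrix mouse arrays, 1 array per sample. Pregnant ICR mice, an outbred stock, had received 1 of 4 injections, and each of the 4 groups held 2 arrays that the labels call biological replicates. The labels do not say whether the embryos of a replicate came from 1 litter or several, so the p-values measure the spread between these samples. Biotin-labelled cRNA was made from 5 µg of total RNA, per the labels. The deposited values are probe set intensity on a linear scale, made by the authors with MAS5 per the submitters' processing notes. MAS5 combines the probes of a probe set into 1 signal and scales each array by a single factor. In the deposited table the mean signal after trimming the lowest and highest 2% was 500 on every array, so no further scaling was applied. The software version, the scaling target and any batch of hybridisation are not given in the sources used here. The number of arrays limits the precision, with 4 residual degrees of freedom over all 8.

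Of the 45101 probe sets in the table, 64 were control probe sets. The platform annotation, of 2016, gave exactly 1 gene for 34945 of the others, several genes for 932 and no gene for 9160. Of the single-gene probe sets, 34741 had a symbol found in the reference gene table. Only single-gene probe sets were used, and for each of 18193 genes the probe set with the highest mean log2 value over the 8 arrays was kept. The values were transformed to log2(signal + 9), where 9 is the 10th percentile of all deposited values, rounded. A fold change on this scale understates the change of weakly expressed genes. Genes whose mean lay below the 40th percentile of all probe sets, a log2 value of 6.12 or a signal of 60.3, were left out, which removed 5185 genes and left 13008.

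Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes with a trend on mean level. A single fit of the 4 group means to all 8 arrays gave all groups a common estimate of the spread. Contrasts were 5E1 minus 40-1a, cyclopamine minus PBS, 5E1 minus PBS, 40-1a minus PBS, the mean of both blocking agents minus the mean of both controls, and the difference between the antibody effect and the cyclopamine effect. Adjusted p-values are Benjamini-Hochberg values over the 13008 genes, with a threshold of 0.05. Fold changes are given with the standard error (SE) of the fit, and signals as mean ± SD of 2 arrays.

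Of 32 gene lists fixed before the data were examined, with 542 different genes, 30 had at least 5 genes tested. Probe sets of a single gene covered 507 of these genes, and 453 were tested. The lists were compared with the other genes by camera with a preset correlation of 0.01, adjusted over the 30 lists. Camera with a correlation estimated from the arrays and fry were run beside it. Where a gene's p is given as adjusted over the list alone, the adjustment covers only the tested members of that list. The lists of salivary gland and tongue genes and of sex-linked genes had under 5 genes tested, and their levels are given without a test.

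The genes named in the text follow a rule fixed before the data were examined. It takes, for the pooled, 5E1 and cyclopamine comparisons, every measured Hedgehog target and 7 pathway components. It then takes the 8 genes with the largest rise and the 8 with the largest fall past the threshold whose arrays do not overlap between the sides. Where fewer pass, the next ones by unadjusted p in each direction fill the places, and these did not pass. It also takes up to 4 members of each other list by p in the pooled comparison, and 15 genes of tooth signalling named in advance. For the other comparisons it takes 5 rises and 5 falls. Genes of the Hedgehog and tooth signalling parts within 1 SE of 0 are given only as a count and a range, except Ptch1 and Gli1. That choice, and the choice of examples among the list members, was made after the values were seen.

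The alternatives fixed before the data were examined were quantile normalisation, median centring, 2 other pseudocounts, 2 other filters, other variance models, array weights, 2 other rules for choosing probe sets and the replicate number as a block. Each array was also left out in turn, the compared groups were fitted alone, and a rule of 2-fold change without overlap was counted. After the data were examined 3 alternatives were added. The array cluster block uses as a block the 3 clusters into which the arrays fell by hierarchical clustering of the genes tested. The control probe set block uses clusters found on the 64 control probe sets alone, in which cyclopamine replicate 1 stood by itself and so had no part in the fit. The last left out the arrays of cluster 3. The array cluster block takes its clusters from the same values it is then applied to, so its p-values lean towards calls.

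The fits were tested on simulated data for the 5E1 against 40-1a contrast, with 200 of 13008 genes changed. With spread as measured but independent between arrays, the fit without a block recovered 23.9% of genes changed 2-fold, 88.1% of those changed 4-fold and 98.5% of those changed 8-fold, with 7 false calls among 147. With array clusters added, the recovery without a block was 14.9%, 74.6% and 90.9%, with 0 false calls among 120. With the clusters as a block it was 80.6%, 100% and 100%, with 23 false calls among 210. The clusters were those of the measured arrays and were not found again in the simulated values, so the bias of finding them was not measured. With 200 genes changed the adjusted threshold is easier to reach than where few genes change. These recovery rates therefore do not carry over to the measured data, where Ptch1, at log2 -2.31, had an adjusted p of 0.969 in this contrast. A count of 0 called genes there does not exclude changes of 4-fold. No pair of arrays held the same values, and the largest share of equal values in any pair was 0.00443% of probe sets.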

Results

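The data describe mandibular molar tooth germs 24 hours after a single intraperitoneal injection into pregnant mice at embryonic day 14. Shh, the Hedgehog ligand of the dental epithelium, was blocked in 2 ways. The antibody 5E1 binds the Shh protein and was given at 10 mg/kg, with 40-1a, an antibody of the same isotype against β-galactosidase, as its control at 10 mg/kg. Cyclopamine, an antagonist of the membrane protein Smo that relays the Hedgehog signal, was given at 10 mg/kg, and PBS (1 ml) was injected in the last group. The labels do not state the vehicle of cyclopamine. Each group had 2 arrays.

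The arrays did not group by injection, and their groups differed in markers of epithelium, muscle and mesenchyme. By correlation over the 13008 genes tested, the arrays formed 3 clusters. Cluster 1 held replicate 1 of 5E1, 40-1a and PBS, cluster 2 held replicate 2 of 5E1, 40-1a and cyclopamine, and cluster 3 held cyclopamine replicate 1 and PBS replicate 2. In cluster 2, 26 of 27 dental epithelium genes were higher than in cluster 1, by a mean of 0.76 on the log2 scale, as were all 21 skeletal muscle genes (1.36) and all 15 genes of suprabasal oral epithelium (1.25). Only 1 of 23 dental mesenchyme genes was higher there, with a mean difference of -0.94, and the endothelial mean difference was -0.66. Pearson's r across genes was at least 0.977 between arrays of one cluster and 0.942 to 0.972 between clusters, while the arrays of one group correlated at 0.946 to 0.970. The first principal component held 44.3% of the variance and separated clusters 1 and 2. The place of PBS replicate 2 varied with the probe sets used, since it joined cluster 1 on the control probe sets and cluster 2 on 3428 probe sets without a single gene. Cyclopamine replicate 1 had a mean 18S ribosomal RNA signal of 2548, against 52.9 to 447.6 on the other 7 arrays. The 5E1 and 40-1a groups each had an array in cluster 1 and one in cluster 2, so this contrast was balanced over the clusters, whereas cyclopamine and PBS were not.

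**Figure D1:**
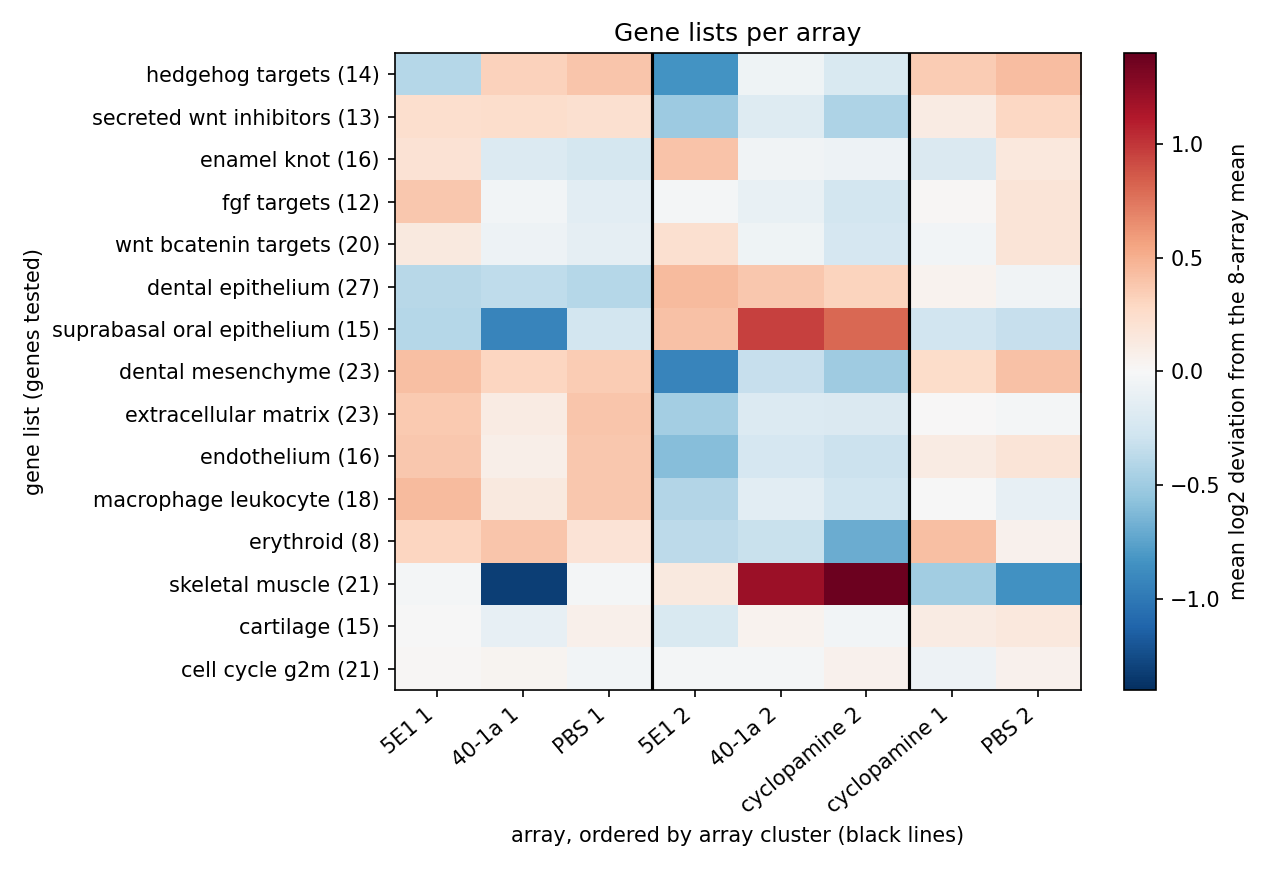
Mean log2 deviation from the 8-array mean (colour) of each gene list (vertical axis, number of genes tested in brackets) on each array (horizontal axis, ordered by array cluster). Skeletal muscle genes ranged from -1.32 on 40-1a replicate 1 to 1.37 on cyclopamine replicate 2, and Hedgehog targets were lowest on 5E1 replicate 2, at -0.84.

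The comparison of 5E1 with 40-1a asks what blocking the Shh protein does with the antibody injection itself held equal. Transcripts of the Hedgehog pathway's own feedback genes were several-fold lower after 5E1. Ptch1, the Hedgehog receptor and a direct target of the pathway, had a signal of 1837 ± 402 after 5E1 and 9251 ± 2930 after 40-1a, 4.95-fold lower (log2 -2.31, SE 0.30). Gli1, a transcription factor induced by the pathway, was 4.65-fold lower (log2 -2.22, SE 0.40), at 293.9 ± 76.6 against 1391 ± 276. Sostdc1, a secreted inhibitor of BMP and Wnt signalling, was 2.26-fold lower (log2 -1.18, SE 0.20), at 4773 ± 527 against 10860 ± 2040. Dusp6, a phosphatase induced by FGF signalling, was 1.59-fold higher (log2 0.67, SE 0.12).

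Over all genes limma called 0 at an adjusted p of 0.05, with 159 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.969 (Ptch1). Adjusted over the list alone, 3 of 14 Hedgehog targets passed, all lower, namely Ptch1 (adjusted p = 0.00104), Gli1 (0.00434) and Hhip (0.0451). Hhip, a Hedgehog-binding antagonist, had a log2 difference of -1.58 (SE 0.46), and its signal of 33.3 ± 2.48 after 5E1 lay below the filter level. Sostdc1 (0.00501, secreted Wnt inhibitors), Dusp6 (0.00720, FGF targets) and Odam (0.00627, tooth mineralisation) passed adjusted over the list alone too. Odam, which encodes a protein of ameloblasts, was 2.41-fold higher (log2 1.27, SE 0.26). Its list held only 5 tested genes and was not higher as a whole. The list mean was -0.03 within cluster 1 (2 genes lower) and -0.35 within cluster 2 (4 lower), with Amelx and Ambn lower in both. With each array left out in turn Ptch1, Gli1, Sostdc1 and Odam passed adjusted over the list alone in all 8 fits. Dusp6 missed the threshold without 5E1 replicate 1 (adjusted p = 0.0652), 5E1 replicate 2 (0.0534) or 40-1a replicate 1 (0.0647), and Hhip passed in 1 of the 8 fits, without 40-1a replicate 2, and was at -1.04 (0.287) without 40-1a replicate 1. With the array cluster block, chosen after seeing the data, limma called 3 genes, all lower: Ptch1 (adjusted p = 0.00107), Gli1 (0.00165) and Sostdc1 (0.0161). Over all alternatives the adjusted p ran from 0.00107 to 1 for Ptch1, from 0.00165 to 1 for Gli1 and from 0.0161 to 1 for Sostdc1. Within cluster 1 the log2 differences between the antibody arrays were -2.41, -2.28 and -1.26 for these 3 genes, and within cluster 2 they were -2.20, -2.16 and -1.10. The control probe set block, also chosen after seeing the data, called Ptch1 alone (adjusted p = 0.00294). The replicate number as a block, planned in advance, called Ptch1 alone too (adjusted p = 0.00519), although the labels name no pairing.

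Hedgehog targets as a group were lower after 5E1, with 10 of 14 genes lower, a mean log2 difference of -0.75 and an adjusted camera p of 3.92e-07 (adjusted p = 0.374 with an estimated correlation). Within clusters 1 and 2 the mean was -0.73 and -0.78. The forkhead genes Foxd2 (-1.52, SE 0.49) and Foxf2 (-1.18, SE 0.62) were lower without overlap. Foxf1 (-0.68, SE 0.66), Foxd1 (-0.55, SE 0.39), Osr2 (-0.66, SE 0.48) and Mycn (-0.36, SE 0.32) overlapped between the groups, as did the cell cycle kinase Cdk6 (0.19, SE 0.18). None of these passed. Without 5E1 replicate 2 the differences were 0.16 for Foxf1, -0.05 for Osr2, -0.03 for Mycn, 0.01 for Cdk6 and -0.89 for Foxd2. Foxf2 was at -0.54 without 40-1a replicate 1 and Foxd1 at -0.25 without 40-1a replicate 2. Of the pathway components, Shh itself was 0.52 higher (SE 0.27; 0.22 without 40-1a replicate 1) and Smo was at -0.18 (SE 0.14), again not past the threshold. The other 9 of the 21 targets and components lay between -0.23 and 0.29. In cluster 2, where mesenchymal markers were lower, the target list was lower than in cluster 1 by a mean of -0.48.

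Signalling genes of the enamel knot, the epithelial centre that directs cusp formation, were higher after 5E1. Of 16 genes, 14 were higher, with a mean log2 difference of 0.42 (camera adjusted p = 4.32e-08, adjusted p = 0.374 with an estimated correlation). Among them were Bmp2 (0.78, SE 0.23), Bmp7 (0.60, SE 0.22), Fgf9 (1.04, SE 0.35) and Fgf20 (1.12, SE 0.50), none of which passed singly. Without 5E1 replicate 2 Fgf9 was at 0.55 and Fgf20 at 0.51, and without 40-1a replicate 1 Bmp7 was at 0.39. Wnt10b (0.85, SE 0.47), Wnt10a (0.47, SE 0.46) and the cell cycle inhibitor Cdkn1a (0.61, SE 0.39) were higher on average, and Bmp4 was lower (-0.72, SE 0.44). Without 5E1 replicate 2 Bmp4 was at -0.01, Wnt10b at 0.31 and Wnt10a at -0.06, and without 40-1a replicate 1 Wnt10a was at -0.09 and Cdkn1a at 0.12. Of the 37 values named for this comparison, 16 moved by over 1.5 times when 1 array was left out. The remaining 8 of the 14 tooth signalling genes measured lay between -0.46 and 0.26.

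FGF targets were higher in 9 of 12 cases, with a mean of 0.25 (camera adjusted p = 5.68e-05, 0.374 as an adjusted p with an estimated correlation), and included Spry2 (0.59, SE 0.18). Within cluster 1 their mean was 0.42 and within cluster 2 it was 0.08. Wnt/β-catenin targets were higher in 16 of 20 cases, with a mean of 0.25 (camera adjusted p = 0.000639, 0.515 as an adjusted p with an estimated correlation). Examples were Apcdd1 (0.79, SE 0.27) and Myc (0.55, SE 0.19). Within clusters 1 and 2, 6 and 5 of the 20 genes were lower, among them Axin2 (-0.197 and -0.00012) and Nkd2 (-0.151 and -0.29). Dkk1 was at 0.353 and -1.27. Edar, Fgf4, Fgf20 and Lef1 are also in the enamel knot list, so the 2 lists are not independent. With the mean of probe sets Spry2 was at 0.12 and Apcdd1 at 0.32. Hypoxia genes (15 of 17 higher, mean 0.17) and immediate early and heat shock genes (13 of 17 higher, mean 0.29) each had a camera adjusted p of 0.00232. With an estimated correlation the adjusted p was 0.668 for the hypoxia genes and 0.515 for the immediate early genes. Against PBS the immediate early genes were at 0.07 after 5E1 (camera adjusted p = 0.182), and at -0.08 with the array cluster block (0.246). Fry called 0 of the 30 lists, with a smallest adjusted p of 0.997. No list of cell type markers passed, with mean differences of 0.01 for dental epithelium (median -0.00, camera adjusted p = 0.953), -0.24 for dental mesenchyme (0.207) and 0.12 for skeletal muscle (0.895). Dental mesenchyme was called lower with the array cluster block (mean -0.24, adjusted p = 0.00133, adjusted p = 0.886 with an estimated correlation). These means cover opposite differences within the clusters. Skeletal muscle differed by 1.30 within cluster 1 and by -1.06 within cluster 2, suprabasal oral epithelium by 0.52 and -0.55, dental mesenchyme by 0.12 and -0.60, endothelium by 0.29 and -0.35, and extracellular matrix by 0.25 and -0.30.

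Among the other genes with the smallest p and no overlap, none passing, Slco4a1, an organic anion transporter, was 3.17-fold lower and the keratin gene Krt36 2.98-fold lower. Ntrk2, the BDNF receptor, was 2.48-fold lower, at 1138 ± 116 against 2841 ± 371, and all 8 of its probe sets had that sign. The sialyltransferase gene St3gal6 was 2.76-fold and Lypd1 2.23-fold lower. Mybpc3, with a signal of 59.9 after 40-1a just below the filter level, was 2.78-fold, Krt73 2.50-fold, Esyt3 2.43-fold, Hspa2 1.90-fold, 1500009L16Rik 1.80-fold and Dach1 1.75-fold higher. Some of these values moved with the choice of probe set. With the mean of probe sets 1500009L16Rik was at a log2 difference of 0.10, Dach1 at 0.43 and St3gal6 at -0.54, and without x and s probe sets St3gal6 was at -0.43 and Slco4a1 at -0.98. A difference of at least 2-fold without overlap was found for 87 genes, 28 higher and 59 lower. Irrespective of size, 19.4% of genes did not overlap, where chance gives 33.3%.

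**Figure D2:**
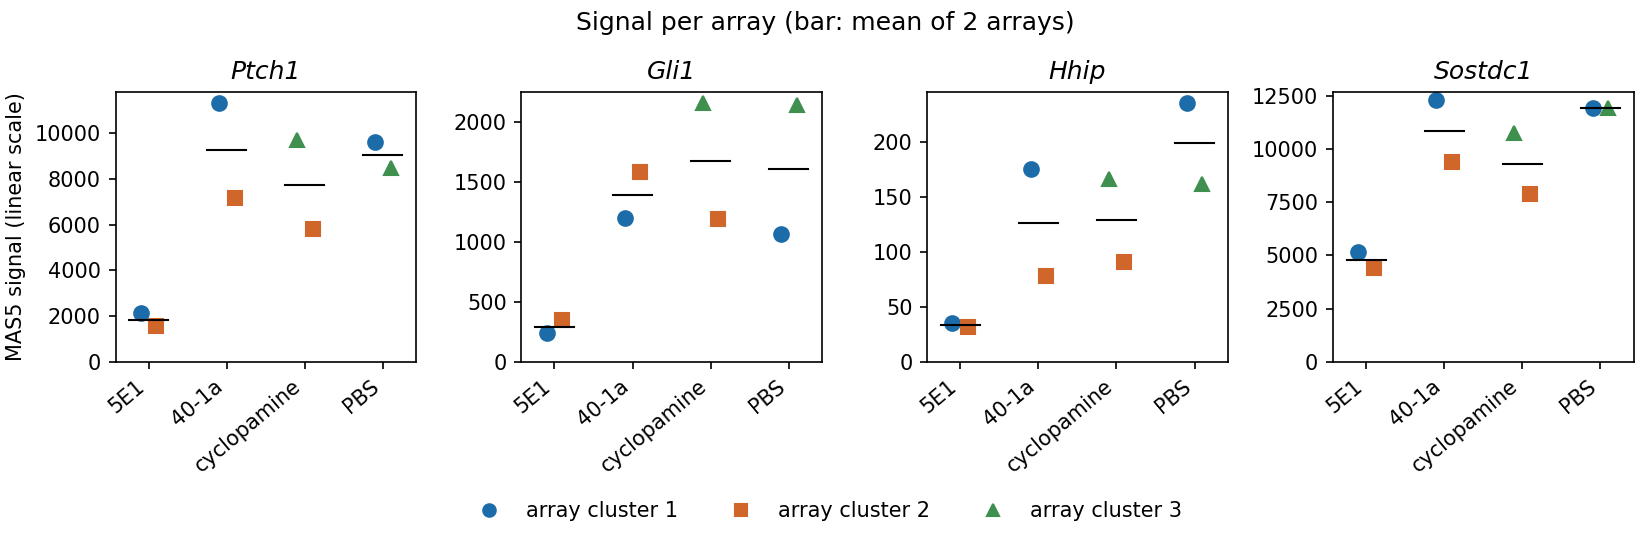
MAS5 signal on a linear scale (vertical axis) of Ptch1, Gli1, Hhip and Sostdc1 on each array (points, with shape and colour for the array cluster) in the 4 groups (horizontal axis), with the mean of 2 arrays as a bar. The 5E1 arrays lie lowest for each gene, with Ptch1 at 2122 and 1552 against 5793 to 11320 on the other 6 arrays.

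Set against PBS in place of 40-1a, the feedback genes were again lower after 5E1. Ptch1 was 4.95-fold lower (log2 -2.31, SE 0.30), Gli1 5.11-fold lower (-2.35, SE 0.40), Hhip 4.84-fold lower (-2.28, SE 0.46, against -1.58 with 40-1a as the control) and Sostdc1 2.50-fold lower (-1.32, SE 0.20). Slco4a1 (-1.59) and Ntrk2 (-1.19) were lower too, and Bcl2l14, Krt73, Rtn1 and 1110032F04Rik were higher, by 1.76, 1.71, 1.70 and 1.34, with Dusp6 at 0.60. The PBS signals of Bcl2l14 and Rtn1 (29.5 and 34.6) lay below the filter level. Between the 5E1 and 40-1a arrays Bcl2l14 differed by only -0.25 within cluster 1 and 0.07 within cluster 2. With the mean of probe sets Bcl2l14 was at 1.03 and 1110032F04Rik at 0.87, and without x and s probe sets Slco4a1 was at -0.76. Hedgehog targets were lower in 12 of 14 cases, with a mean of -1.03 (camera adjusted p = 4.41e-11, adjusted p = 0.438 with an estimated correlation), and 4 passed adjusted over the list alone. Of these, Foxd2 missed the threshold without 5E1 replicate 2 (-1.06, adjusted p = 0.190), PBS replicate 1 (0.143) or PBS replicate 2 (0.0882), and Hhip without PBS replicate 1 (0.0615). FGF targets were called higher (mean 0.16, camera adjusted p = 0.00871, adjusted p = 0.512 with an estimated correlation), but their median was -0.03 and 5 of 12 were higher. Within cluster 1, the only cluster with both groups, their mean was 0.53 with 10 of 12 higher, in 1 pair of arrays. Dental mesenchyme genes were lower (mean -0.63, camera adjusted p = 6.96e-06, adjusted p = 0.588 with an estimated correlation), and with the array cluster block their mean was -0.20. Limma called 0 genes over all genes tested, with 193 at an unadjusted p under 0.05 and a smallest adjusted p of 0.965. With the array cluster block Ptch1 (log2 -2.01, adjusted p = 0.00782) and Gli1 (-1.99, 0.00955) were called, and the smallest adjusted p over the alternatives ran from 0.00517 to 1. The planned replicate block called Ptch1 (adjusted p = 0.00517), although the labels name no pairing. At least 2-fold without overlap were 35 higher and 101 lower genes, and 22.3% of genes did not overlap, where chance gives 33.3%.

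The comparison of cyclopamine with PBS asks for the effect of blocking Smo. No difference in the feedback genes was detectable after cyclopamine on these arrays. The signal of Ptch1 was 7738 ± 2750 after cyclopamine and 9042 ± 804 after PBS (log2 -0.27, SE 0.30, 95% interval -0.97 to 0.44). Gli1 was at 1675 ± 682 and 1607 ± 759 (log2 0.08, SE 0.40, 95% interval -0.85 to 1.01). Sostdc1 (-0.37, SE 0.20) and Hhip (-0.63, SE 0.46) did not pass either, and with 1 array left out they ran from -0.60 to -0.15 and from -1.04 to -0.22. By camera with the preset correlation, lists of cell type markers were called, epithelial and muscle genes higher and mesenchymal, endothelial and matrix genes lower, but each had an adjusted p of 0.615 with an estimated correlation and fry called 0 lists (smallest adjusted p of 0.851). The same marker groups separated the array clusters.

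Limma called 0 genes, with 205 at an unadjusted p under 0.05, and a smallest adjusted p of 0.983. The array cluster block called 0 as well, with a smallest adjusted p of 0.228. The sign for Gli1 depended on the setting, at -0.34 without cyclopamine replicate 1, -0.42 without PBS replicate 1, -0.12 with the array cluster block and -0.81 (SE 0.48) with the control probe set block. Ptch1 was at -0.64 without cyclopamine replicate 1, 0.10 without cyclopamine replicate 2 and 0.04 with the array cluster block. Its largest difference was -0.73 (SE 0.40) with 6 arrays, without those of cluster 3, and with the mean of probe sets it was -0.55 (SE 0.28). Within cluster 3, the only cluster with both groups, the difference was 0.19 for Ptch1 and 0.01 for Gli1.

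Hedgehog targets as a list were lower in 10 of 14 cases, with a mean of -0.34 and a camera adjusted p of 0.0438 (adjusted p = 0.615 with an estimated correlation). The lower members included Foxf1 (-1.16, SE 0.66), Foxd1 (-0.98, SE 0.39), Osr2 (-0.70, SE 0.48), Foxf2 (-0.67, SE 0.62) and Mycn (-0.34, SE 0.32), and 0 passed adjusted over the list alone. Without cyclopamine replicate 2 Foxf2 was at 0.27, Osr2 at -0.18 and Foxf1 at -0.63, without PBS replicate 2 Mycn was at -0.05, and without PBS replicate 1 Foxd1 was at -0.61. With the array cluster block the mean of the list was -0.12 (adjusted p = 0.451), with Foxf1, Osr2 and Foxf2 at -0.44, -0.27 and -0.14. The control probe set block gave -0.09 for Foxf1 and -0.29 for Osr2, and the fit with 6 arrays gave -1.59 for Foxf2 and -1.52 for Foxd1. Cdk6 (0.40, SE 0.18) and Smo (0.15, SE 0.14) had positive values, at 0.26 and 0.05 without cyclopamine replicate 1. The other 11 of the 21 targets and components lay between -0.46 and 0.14.

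Camera with the preset correlation called 7 lists of tissue markers, each with an adjusted p of 0.615 with an estimated correlation. Dental epithelium genes were higher in 25 of 27 cases (mean 0.41, camera adjusted p = 1.76e-05), for example Krt8 (0.62, SE 0.34). All 15 suprabasal genes were higher (mean 0.56, camera adjusted p = 0.00486), as were 20 of 21 skeletal muscle genes (mean 0.87, camera adjusted p = 0.00152), and for both lists the adjusted p was 0.615 with an estimated correlation. Myh8, a myosin of developing muscle, was at 404.5 ± 300 against 49.9 ± 14.1. Lower on average were dental mesenchyme (21 of 23, mean -0.50, adjusted p = 0.000448), endothelium (13 of 16, mean -0.38, adjusted p = 0.00207), macrophage genes (16 of 18, mean -0.28, adjusted p = 0.00385) and extracellular matrix (21 of 23, mean -0.28, adjusted p = 0.00440). With an estimated correlation the adjusted p of these 4 was 0.615 as well. Examples were Fgf10 (-1.30, SE 0.64) and Pecam1 (-0.84, SE 0.43). With the control probe set block Krt8, Fgf10 and Pecam1 were at -0.04, 0.03 and 0.03. Fgf10 was at -0.45 without cyclopamine replicate 1, and its signal after cyclopamine (34.3), like that of Myh8 after PBS, lay below the filter level. The array cluster block gave means of 0.03, -0.08, 0.23, -0.04, -0.06, 0.03 and 0.02 in the order given, and none was called.

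Hypoxia genes were higher in 17 of 17 cases, with a mean of 0.34 (camera adjusted p = 1.76e-05, adjusted p = 0.615 with an estimated correlation), among them the glucose transporter Slc2a1 (0.44, SE 0.17). Their mean was 0.24 with the array cluster block (adjusted p = 0.00662, adjusted p = 0.716 with an estimated correlation). Within cluster 3 it was 0.32, in a pair that includes cyclopamine replicate 1, the array with the highest 18S signal, and cyclopamine replicate 2 lay above the 40-1a array of cluster 2 by 0.11. Hypoxia genes also differed between the clusters, with 15 of 17 higher in cluster 2 than in cluster 1 (mean 0.28). Secreted Wnt inhibitors were lower in 11 of 13 cases (mean -0.42, camera adjusted p = 0.000914, adjusted p = 0.615 with an estimated correlation), for example Dkk3 (-0.92, SE 0.25) and Wif1 (-0.91, SE 0.39). With the control probe set block Dkk3, Wif1 and Slc2a1 were at -0.30, -0.11 and 0.18. The mean of the Wnt inhibitors with the array cluster block was -0.14 (adjusted p = 0.0692). BMP targets (mean -0.13, camera adjusted p = 0.0334) and genes of the Eda and NF-κB pathway (0.25, 0.0438) passed with the preset correlation, and each had an adjusted p of 0.615 with an estimated one. Enamel knot genes did not pass (mean -0.08, camera adjusted p = 0.450), and with the block their mean was -0.20 (adjusted p = 0.0103). The block also called Wnt/β-catenin targets (-0.20, adjusted p = 0.00662) and immediate early genes (-0.26, adjusted p = 0.0315), and with an estimated correlation in this fit the adjusted p of all 3 lists was 0.716. In cluster 3, in the pair with cyclopamine replicate 1, the means were -0.35, -0.22 and -0.30 for enamel knot, Wnt target and immediate early genes. Cyclopamine replicate 2 differed from the 40-1a array of cluster 2 by -0.02, -0.18 and 0.17. Dusp6 was at -0.29 (SE 0.12), Lef1 at -0.71 (SE 0.39), Wnt10a at 0.48 (SE 0.46, 0.16 without PBS replicate 1) and Fgf4 at -0.46 (SE 0.35, -0.10 without PBS replicate 2), and the other 10 tooth signalling genes lay between -0.43 and 0.35. Lef1 was at -0.27 with the array cluster block and 0.006 with the control probe set block. Wnt10a was at -0.058 and -0.398 with these blocks and at 0.998 with 6 arrays.

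None of the genes with the smallest p after cyclopamine was a Hedgehog target of the list, and none passed. The cornified envelope gene Lce1h was 6.70-fold lower, at 31.8 ± 12.9 against 268.8 ± 113. Ppwd1, a peptidyl-prolyl isomerase gene, was 2.91-fold, Rslcan18 2.90-fold, AU021092 2.88-fold, Leng9 2.54-fold, the mitochondrial sirtuin gene Sirt4 2.16-fold, Gpank1 2.14-fold and Smim10l1 1.60-fold lower. Smad2 was 3.19-fold, Rtn1 2.79-fold, Bcl2l14 2.53-fold, Ahnak2 2.20-fold, Dusp16 2.02-fold, Ppfia3 1.94-fold, Dnajb2 1.78-fold and Ndufv1 1.60-fold higher. The folds of 6 of these genes rest on a group mean below the filter level of 60.3, where the signal limits their precision, namely Lce1h, AU021092, Rslcan18 and Leng9 after cyclopamine (17.9 to 40.8) and Bcl2l14 and Rtn1 after PBS (29.5 and 34.6). Smad2 had 1 of 2 probe sets with this sign, its signal was 557.4 and 168 on the PBS arrays, and its log2 difference was 0.83 without PBS replicate 2 and 0.50 with the mean of probe sets. With that mean Leng9 was at -0.31, Gpank1 at -0.53 and Ndufv1 at 0.44, and without x and s probe sets Leng9 was at -0.12. With the control probe set block Rtn1, Dusp16 and Dnajb2 were at 0.91, 0.43 and 0.33. Smad2, Bcl2l14 and Lce1h also differed in the same direction between 40-1a and PBS. The log2 differences there were 1.78 for Smad2 and, over the alternatives, 1.34 to 2.11 for Bcl2l14 and -2.76 to -1.59 for Lce1h. Cyclopamine replicate 2 differed from the 40-1a array of cluster 2 by -0.485, -0.313 and -0.311 for these genes. Their differences from PBS are thus not particular to cyclopamine. Of the 38 values named for this comparison, 15 moved by over 1.5 times when 1 array was left out. A difference of at least 2-fold without overlap was found for 124 genes, 39 higher and 85 lower, and 32.2% of all genes did not overlap, where chance gives 33.3%.

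**Figure D3:**
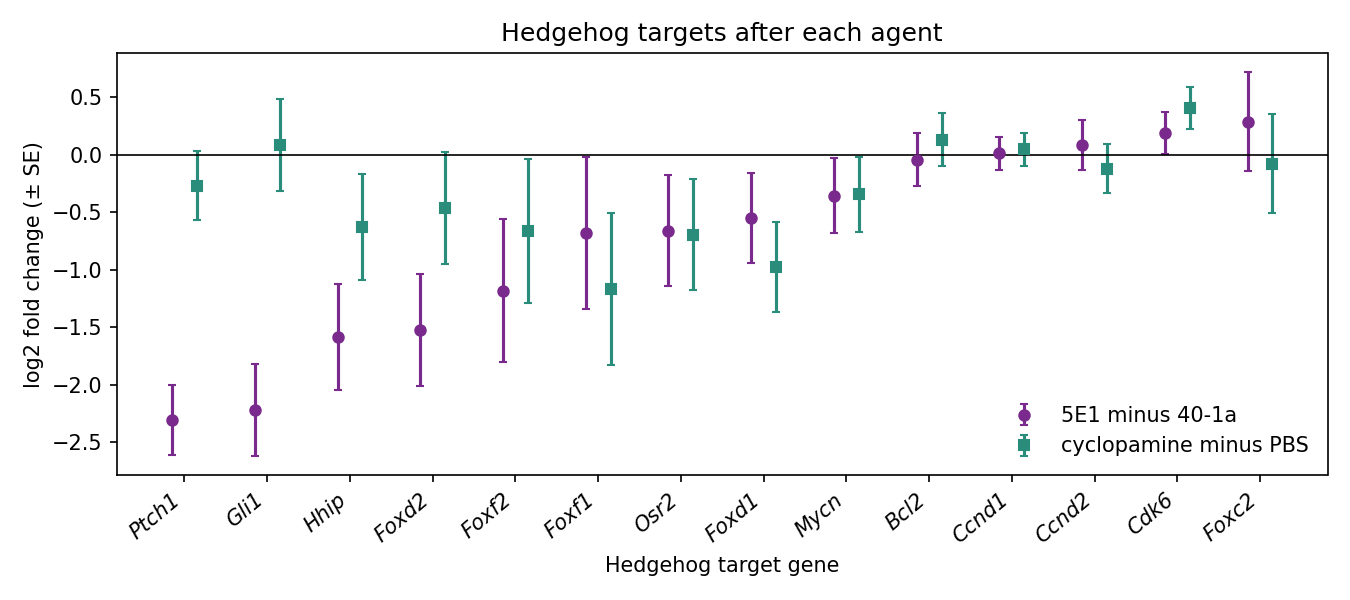
Log2 fold change with its SE (vertical axis) of the Hedgehog target genes (horizontal axis) for 5E1 against 40-1a and for cyclopamine against PBS, from 2 arrays per group. Ptch1 and Gli1 lie at -2.31 and -2.22 for 5E1 and at -0.27 and 0.08 for cyclopamine.

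The difference between the 2 effects was tested directly. For Ptch1 the antibody effect was lower than the cyclopamine effect by a log2 difference of -2.04 (SE 0.43, 95% interval -3.03 to -1.04), and for Gli1 by -2.30 (SE 0.57, 95% interval -3.62 to -0.98). Adjusted over the list alone both passed, with adjusted p of 0.0221 and 0.0274. Neither passed without cyclopamine replicate 1 (-1.67 for Ptch1, adjusted p = 0.0823, and -1.88 for Gli1, 0.121) or PBS replicate 1 (-2.13, 0.0674, and -1.80, 0.0880), and Ptch1 also missed the threshold without PBS replicate 2 (0.0522) and Gli1 without 5E1 replicate 1 (0.0853) or 40-1a replicate 2 (0.0915). Dusp6 (1.95-fold, adjusted p = 0.00641) and Odam (2.82-fold, adjusted p = 0.0179) passed adjusted over the list alone in the other direction, and Odam missed the threshold without 5E1 replicate 1 (0.0641), 40-1a replicate 2 (0.0564), cyclopamine replicate 2 (0.0701) or PBS replicate 2 (0.0723). Limma called 0 genes over all genes tested, with 187 at an unadjusted p under 0.05. With the array cluster block 3 were called, Ptch1 (-2.35, adjusted p = 0.0172), Gli1 (-2.10, 0.0294) and the immediate early gene Fos (3.08, 0.0294). Fos lies outside the naming rule and was named after its value was seen, and its log2 difference without a block was 2.25. The smallest adjusted p over the alternatives ran from 0.0172 to 1. Of the other genes named by their small unadjusted p, none passing, Krt36 (-2.13), Slco4a1 (-1.78) and Ntrk2 (-1.54) were lower. Mybpc3 (1.95), Ppwd1 (1.81), Sirt4 (1.65) and 1500009L16Rik (1.14) were higher. With the mean of probe sets Ntrk2 was at -0.62 and 1500009L16Rik at 0.52. Of the lists, 8 were higher and 3 lower by camera, led by enamel knot genes (mean 0.51, adjusted p = 4.67e-05, adjusted p = 0.467 with an estimated correlation). Across all genes, which are not independent replicates, the fold changes of the agents had a Pearson's r of 0.0423 and a Spearman's rho of 0.0156. Pairing single arrays in 16 ways gave r from -0.645 to 0.615, so the arrays do not settle the sign of this correlation. The 5E1 minus 40-1a difference within cluster 1 correlated with that within cluster 2 at only r = 0.0111 (rho 0.0434). An r near 0 between the agents therefore does not show that they move different genes.

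Taking both agents together, 4 arrays against 4, Ptch1 was 2.44-fold lower (log2 -1.29, SE 0.21), Gli1 2.10-fold lower (-1.07, SE 0.28), Hhip 2.15-fold lower (-1.11, SE 0.33) and Sostdc1 1.71-fold lower (-0.78, SE 0.14). These 4 genes passed adjusted over the list alone, with adjusted p of 0.00512, 0.0408, 0.0478 and 0.00788, although the arrays of the sides overlapped for each. Ptch1 and Sostdc1 passed with each array left out in turn, Gli1 in 4 of 8 such fits (highest adjusted p = 0.145, without cyclopamine replicate 2) and Hhip in 3 of 8 (0.180, without PBS replicate 1). The values average the effects of 5E1 and cyclopamine, which differed for Ptch1 and Gli1 adjusted over the list alone. Limma called 0 genes over all genes tested, with 159 at an unadjusted p under 0.05 and a smallest adjusted p of 1. With the array cluster block Ptch1 and Gli1 were called, both lower at an adjusted p of 0.0205, and the smallest adjusted p over the alternatives ran from 0.0205 to 1. The planned replicate block called Ptch1 (adjusted p = 0.0306), although the labels name no pairing.

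Hypoxia genes were higher in 17 of 17 cases in the pooled comparison (mean 0.25, camera adjusted p = 5.10e-08, adjusted p = 0.611 with an estimated correlation), with Slc2a1 at 0.33 (SE 0.12) and Bnip3 at 0.41 (SE 0.18). Hedgehog targets were lower in 10 of 14 (mean -0.55, camera adjusted p = 9.53e-07, adjusted p = 0.611 with an estimated correlation). Both were called with the array cluster block (means 0.20 and -0.44, adjusted p of 2.34e-06 and 1.22e-07, adjusted p = 0.528 with an estimated correlation). Bnip3 was at 0.23 without 5E1 replicate 2. Secreted Wnt inhibitors (mean -0.30, adjusted p = 0.000841), enamel knot genes (0.17, 0.00780) and Eda and NF-κB genes (0.14, 0.0277) passed with the preset correlation and had an adjusted p of 0.675 with an estimated one. The other 7 of the 12 lists called were markers of tissue types. Dental epithelium (0.21), skeletal muscle (0.50) and suprabasal epithelium (0.27) were higher, and dental mesenchyme (-0.37), endothelium (-0.20), osteoblast (-0.19) and matrix (-0.15) lower. Their adjusted p with an estimated correlation was 0.675 for osteoblast genes and 0.753 for the others. With the block only dental mesenchyme of these 7 was called, at a mean of -0.14 (adjusted p = 0.0325, adjusted p = 0.985 with an estimated correlation).

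Of single genes in the pooled comparison, none passing, Foxd2 (-0.99, SE 0.34), Foxf2 (-0.92, SE 0.44), Foxf1 (-0.92, SE 0.47), Foxd1 (-0.76, SE 0.28), Osr2 (-0.68, SE 0.34) and Mycn (-0.35, SE 0.23) were lower. Scube1, which encodes a secreted protein, was at -1.30 (SE 0.50). Shh was at 0.24 (SE 0.19) and Cdk6 at 0.30 (SE 0.13), and the other 10 targets and components lay between -0.15 and 0.16. Of the tooth signalling genes, Bmp2 (0.50, SE 0.16), Cdkn1a (0.48, SE 0.28), Wnt10a (0.47, SE 0.32) and Wnt10b (0.35, SE 0.33) were higher, Bmp4 (-0.57, SE 0.31), Dkk1 (-0.44, SE 0.33) and Lef1 (-0.30, SE 0.27) lower, and the other 6 lay between -0.23 and 0.21. Of the 38 values named for the pooled comparison, 14 moved by over 1.5 times when 1 array was left out. Nearest to 0 they were, without 5E1 replicate 2, -0.04 for Dkk1, -0.22 for Bmp4, 0.08 for Wnt10b, -0.50 for Foxf1, -0.37 for Osr2 and -0.19 for Mycn, without 40-1a replicate 1, -0.04 for Lef1, 0.09 for Shh, 0.23 for Cdkn1a and 0.19 for Wnt10a, and without cyclopamine replicate 2, -0.46 for Foxf2 and -0.78 for Scube1. The array cluster block gave 0.20 for Wnt10a, 0.25 for Cdkn1a and -0.083 for Lef1, and the control probe set block gave 0.034, 0.13 and 0.055. With 6 arrays Wnt10a was at 0.73 and Lef1 at -0.456. Without overlap between the 4 and 4 arrays, Rtn1 was 2.25-fold, Uroc1 1.92-fold, 1110032F04Rik 1.89-fold, Ahnak2 1.68-fold, Il1r1 1.54-fold, Fbxo4 1.52-fold, Lrp11 1.48-fold and Manbal 1.41-fold higher. Etv2 was 2.47-fold, Plk5 2.31-fold, the growth factor gene Hgf 2.23-fold, St3gal6 2.03-fold, Dlx6os1 1.98-fold, Cxcl17 1.75-fold, Rflna 1.49-fold and Smim10l1 1.30-fold lower. Etv2 was at -0.87 on the log2 scale without 5E1 replicate 1. With the mean of probe sets 1110032F04Rik was at 0.34, Uroc1 at 0.24, St3gal6 at -0.38 and Rflna at -0.97. The signals of Etv2, Plk5 and Hgf after 5E1 (36.5, 42.2 and 51.1), of Etv2 and Cxcl17 after cyclopamine (49.2 and 55.9) and of Rtn1 after PBS lay below the filter level of 60.3. At least 2-fold without overlap were 1 higher and 6 lower genes, and 1.37% of genes did not overlap, where chance gives 2.86%.

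The comparison of the controls shows what differed between tooth germs after an unrelated antibody and after PBS. Neither Ptch1 (log2 -0.00, SE 0.30) nor Gli1 (-0.14, SE 0.40) passed, and both signs depended on the setting. Bcl2l14, of the Bcl-2 family, was 3.61-fold higher after 40-1a, at 129.2 ± 2.81 against 29.5 ± 5.75, and Smad2 3.44-fold, Mup10 3.14-fold, Ankrd33b 2.25-fold and Izumo4 1.94-fold higher. Lce1h was 4.52-fold, Nanos1 3.05-fold, E530011L22Rik 2.89-fold, 2610316D01Rik 2.33-fold and Mybpc3 2.17-fold lower. Without PBS replicate 2 Smad2 was at 0.94 on the log2 scale and with the mean of probe sets at 0.38, without x and s probe sets 2610316D01Rik was at -0.47, and without 40-1a replicate 2 E530011L22Rik was at -0.98. Group means below the filter level of 60.3 enter the folds of 7 of these genes, namely Bcl2l14, Mup10 (38.3) and Ankrd33b (41.8) after PBS and Nanos1 (24.9), E530011L22Rik (39.3), Lce1h (54.8) and Mybpc3 (59.9) after 40-1a. Limma called 0 genes, with 88 at an unadjusted p under 0.05, a smallest adjusted p of 1, and 0 called with the array cluster block. Dental epithelium genes were higher in 25 of 27 cases (mean 0.24, camera adjusted p = 0.000112) and dental mesenchyme genes lower in 21 of 23 (mean -0.40, adjusted p = 0.00111), each with an adjusted p of 0.740 with an estimated correlation. Neither was called with the array cluster block, at means of 0.08 and 0.04. By camera the block called 4 lists, all lower after 40-1a. They were skeletal muscle (-0.62, adjusted p = 6.38e-05), immediate early (-0.37, 1.31e-05), suprabasal (-0.29, 0.00185) and neuronal and Schwann cell genes (-0.39, 0.0144). Each had an adjusted p of 0.903 with an estimated correlation. The 40-1a arrays lay on both sides of the PBS arrays for skeletal muscle, at -1.32 and 1.20 against -0.03 and -0.84. The same held for suprabasal genes, at -0.92 and 0.96 against -0.26 and -0.32. In cluster 1, the only cluster with both groups, the differences of the 4 lists were -1.30, -0.30, -0.66 and -0.26, in 1 pair of arrays. At least 2-fold without overlap were 24 higher and 30 lower genes, and 20.5% of genes did not overlap, where chance gives 33.3%.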

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

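The tests of tissue make-up, of labelling and of treatment as the source of the array clusters, all tests on the cyclopamine arrays, the array cluster block itself and the random partitions that test it were chosen after the results were seen, while the splits of the arrays were planned before.

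The effects of 5E1 and cyclopamine, each against its own control, differed in a direct test for 4 genes adjusted over the list alone and for 11 gene lists by camera with the preset correlation. The log2 differences were -2.30 for Gli1, -2.04 for Ptch1, 0.96 for Dusp6 and 1.497 for Odam. Over all genes tested limma called 0 in this comparison, and the adjustment over the list alone does not correct for the number of lists. The list of Odam held only 5 tested genes. With single arrays left out in turn, Dusp6 passed adjusted over the list alone in 8 of 8 fits, Ptch1 in 5, and Gli1 and Odam in 4 each. Of the lists of signalling genes, the mean difference was 0.51 for enamel knot genes, 0.41 for Wnt/β-catenin targets, 0.42 for FGF ligands and receptors and 0.38 for FGF targets, and for each the adjusted p was 0.467 with an estimated correlation. Immediate early and heat shock genes differed by 0.44. Of the tissue markers, dental epithelium differed by -0.39, suprabasal oral epithelium by -0.57, skeletal muscle by -0.75, endothelium by 0.34, macrophage genes by 0.31 and extracellular matrix by 0.26. With an estimated correlation the adjusted p of these 7 lists was 0.760. In the fit with the array cluster block Hedgehog targets were called at a mean of -0.63 and FGF ligands and receptors were not (adjusted p = 0.0635), while the enamel knot, Wnt target, FGF target and immediate early lists were called at means of 0.63, 0.44, 0.29 and 0.56. With an estimated correlation in this fit each of the 5 called lists had an adjusted p of 0.287, and none of the 6 tissue lists was called.

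The signals of the control features of the array, which were not among the genes tested, set cyclopamine replicate 1 apart. Its 18S ribosomal RNA signal was 2548, and the highest of the other arrays was 447.6. The 3′ to 5′ signal ratios of the bacterial spike-in transcripts were 4.94 for Dap, 4.95 for Phe, 5.04 for Thr and 5.50 for Lys on this array. On the other 7 arrays they reached at most 2.10, 1.85, 2.58 and 3.96.

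The arrays fell into clusters that cut across treatment, and 0 of 8 arrays were closest to the other array of their own group, which argues against treatment as the source. A different share of epithelium and mesenchyme in the dissected tissue may contribute, since 97.6% of 42 epithelial genes were higher in cluster 2 than in cluster 1 and 91.8% of 61 mesenchymal, matrix and endothelial genes lower. Labelling or RNA handling that differed between arrays may contribute too, since 3 of 4 spike-in transcripts, which are not made by the tissue, had ratios that did not overlap between these clusters. Both stay open and neither excludes the other, and the age or litter of the embryos was not tested.

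The lower Ptch1, Gli1 and Sostdc1 after 5E1 were called with the array clusters as a block. Of 100 random partitions of the arrays into 3, 3 and 2, the real one included, 2 called at least 3 genes, and the other one called 128. A random block of this shape thus rarely made such calls. Random partitions are not found on the values and leave the cluster differences in the residual spread. They therefore cannot test a block that was found on the values. The clusters were found on the same values, so the count stays a hypothesis. In simulated data this block gave 23 false calls among 210. That simulation took the clusters as given, so it does not measure the bias of finding them on the same values. The 5E1 array lay below the 40-1a array for all 3 genes within cluster 1 and within cluster 2.

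Ptch1 and Gli1 were not detectably lower after cyclopamine. Low quality of cyclopamine replicate 1 is an unlikely full explanation, since replicate 2 differed from the 40-1a array of its cluster by at most -0.41 for either gene. This rests on 1 array of each group. In the fit without replicate 1 the differences after cyclopamine were -0.64 for Ptch1 and -0.34 for Gli1. The lower bounds of the 95% intervals reached -1.44, above the 5E1 values of -2.31 and -2.22. That reading leaves out the error of the 5E1 values, so it is not a test of the difference, and a smaller fall remains inside the intervals. With the array cluster block both intervals of the difference between the effects excluded 0, with the nearest bound at -1.65. That argues only weakly against the clusters hiding a fall as large as that after 5E1. The clusters were found on the same values, and the only cyclopamine and PBS pair within a cluster includes cyclopamine replicate 1. The control probe set block, in which that array has no part, rests on 1 cyclopamine array. There the difference was -2.22 for Ptch1 and -1.41 (SE 0.56) for Gli1. A weaker or shorter block of the pathway at this dose and time may apply and cannot be told apart from no block, because only 1 dose of cyclopamine was measured.

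For the pooled comparison the 8 arrays allow 35 splits into 4 and 4. In the 2-group fit the real split called 0 genes and the highest other gave 1318. All 35 splits give at least 0, so this count decides nothing about chance. At an unadjusted p under 0.05 the real split gave 214 genes, 26 of 35 splits gave as many and the highest other gave 3833, so chance is not excluded there. The split with the most genes set replicate 1 arrays against replicate 2 arrays, which points to a structure of the arrays other than treatment.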

How the results depend on the processing

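The array cluster block, the control probe set block and the fit without the arrays of cluster 3 (6 arrays) were chosen after the results were seen, and the other settings were planned. The number of called genes stayed at 0 in all 6 comparisons under the other scalings, pseudocounts, filters, variance models, array weights, probe set rules and sample choices, with 6 arrays, and without any single array. The named fold changes leave out Hedgehog and tooth signalling genes within 1 SE of 0, other than Ptch1 and Gli1. That choice was made after the values were seen, and such values change sign most easily, so the next count overstates the stability. Of 147 named fold changes, 128 kept their sign under every setting run. Values moved by over 1.5 times for 32 of those tested with the mean of probe sets, 8 without x and s probe sets, 22 with the array cluster block, 35 with the control probe set block, 22 with 6 arrays and at most 2 with any other setting apart from leaving out single arrays. The robust and no-trend settings were not run for the lists, although the camera tests used the trend. These settings and array weights were not run for the correlation, since they do not change the fold changes it uses. The array weights were equal for the 2 arrays of each group (1.05 for both cyclopamine arrays), so they could not set cyclopamine replicate 1 apart. With 2 arrays per group a lone array is assumed to vary like the other groups when its partner is left out. The cause of the changes below was not tested, apart from the smaller residual spread that a block leaves.

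The labels do not say that arrays of one replicate number belong together, so the numbers were not taken as pairs. The deviations of same-numbered arrays correlated at 0.00157 for cyclopamine with PBS. For the other pairs of groups they correlated at 0.323 to 0.591, so there the arrays shared variation by replicate number. The replicate block called 1 gene (Ptch1) in the pooled comparison (adjusted p = 0.0306), 1 in 5E1 against 40-1a (0.00519) and 1 in 5E1 against PBS (0.00517), and changed no other call, within ranges over the alternatives of 0.0205 to 1, 0.00107 to 1 and 0.00517 to 1.

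The rule of 2-fold without overlap counted 7 genes pooled, 87 for 5E1 against 40-1a, 124 for cyclopamine against PBS and 54 for 40-1a against PBS. For 5E1 against PBS it counted 35 higher and 101 lower genes. The array cluster block called 2, 3, 2 and 3 genes for the pooled, 5E1 against 40-1a and 5E1 against PBS comparisons and the difference of the effects. The control probe set block called 1 gene in 5E1 against 40-1a and 1 in 5E1 against PBS. Lists called fell from 12, 6 and 12 (pooled, 5E1, cyclopamine) to 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. In the array cluster block fit 7, 7 and 4 lists were called (0, 0 and 0 with an estimated correlation), and in the control probe set block fit 1, 7 and 3. Without single arrays the lists called ranged from 2 (without cyclopamine replicate 2) to 14 pooled, with 4 without 5E1 replicate 2 and 7 without 40-1a replicate 1 or PBS replicate 1, from 6 to 15 (without 5E1 replicate 1) for 5E1, with 11 without 5E1 replicate 2 or 40-1a replicate 2, and from 2 (without cyclopamine replicate 2) to 14 for cyclopamine, with 6 without PBS replicate 2. The correlation of the effects ranged from -0.398 (without 5E1 replicate 2) to 0.410 (without 5E1 replicate 1), with -0.377 and 0.384 without 40-1a replicates 1 and 2.

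Of the log2 fold changes that changed sign, none was called. With the mean of probe sets Cdk6 was at -0.071 pooled, -0.083 for 5E1 and -0.059 for cyclopamine, Smo at 0.13 for 5E1 (0.077 without x and s probe sets), Mycn at 0.089 for cyclopamine and Ptch1 at 0.28 for 40-1a against PBS. There Ptch1 was at 0.021 with median centring, 0.295 with the array cluster block and 0.275 with the control probe set block, and -0.33 to 0.33 without single arrays, and Gli1 at 0.22 with the array cluster block, 0.36 with 6 arrays and -0.63 to 0.36 without single arrays. For cyclopamine the array cluster block gave -0.12 for Gli1, 0.045 for Ptch1 and -0.058 for Wnt10a. The control probe set block gave -0.81 for Gli1, 0.0064 for Lef1, 0.011 for Mycn, -0.40 for Wnt10a, -0.038 for Krt8, 0.028 for Pecam1 and 0.033 for Fgf10, and 0.055 for Lef1 pooled. Fgf4 was at 0.11 with 6 arrays. Without single arrays Gli1 ranged from -0.42 to 0.58, Ptch1 from -0.64 to 0.10 and Foxf2 from -1.60 to 0.27 after cyclopamine, and Foxf1 from -1.51 to 0.16 and Wnt10a from -0.094 to 1.02 after 5E1. Signal over background limits the weak genes, since Hhip lay below the filter level of 60.3 after 5E1.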

Other observations

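The tests below use lists fixed before the data were examined, and the lists singled out were chosen after their values were seen. No difference in proliferation genes was detected after either agent. For 21 genes of G2 and M phase the mean log2 difference was -0.01 after 5E1 (camera adjusted p = 0.968) and -0.01 after cyclopamine (0.649), and for 23 S phase genes it was 0.01 (0.901) and -0.03 (0.458). For G2 and M phase genes after 5E1 the camera direction was upward although the mean and the median were negative. Genes of p53 responses were at 0.12 after 5E1 (0.207) and 0.07 after cyclopamine (0.515). Cholesterol synthesis genes were at -0.02 (0.968) and -0.05 (0.362), and interferon response genes at -0.08 (0.895) and -0.01 (0.980). Wnt ligands and receptors differed by 0.06 (0.349) and 0.04 (0.953), BMP ligands and antagonists by -0.02 (0.968) and -0.11 (0.450), and Hedgehog pathway components by -0.01 (0.953) and -0.04 (0.993). FGF ligands and receptors were at 0.13 after 5E1 (0.286) and -0.29 after cyclopamine (0.0978).

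Markers of further tissues also did not pass for either agent against its own control in the fit without a block. Osteoblast genes were at -0.18 after 5E1 (camera adjusted p = 0.0989) and -0.20 after cyclopamine (0.243), and set against PBS all 11 were lower after 5E1 (mean -0.49, 6.96e-06, adjusted p = 0.438 with an estimated correlation). Within cluster 1, the only cluster with both groups, the mean was -0.23 with 8 of 11 lower. Cartilage genes were at -0.08 (0.968) and -0.07 (0.649), erythroid genes at -0.07 (0.895) and -0.26 (0.0729), neuronal and Schwann cell genes at -0.06 (0.986) and -0.12 (0.458), and 5 tooth mineralisation genes at -0.19 (0.968) and -0.30 (0.173). In cluster 2 erythroid genes were at -0.75 relative to cluster 1 and osteoblast genes at -0.50.

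Skeletal muscle genes differed widely between the 2 arrays of some groups, but little between the 5E1 arrays. Their mean deviation was -1.32 and 1.20 on the 40-1a arrays, -0.49 and 1.37 on the cyclopamine arrays, -0.03 and -0.84 on the PBS arrays, and -0.02 and 0.14 on the 5E1 arrays. The 3 salivary gland and tongue genes tested ranged from -0.42 on 40-1a replicate 1 to 0.45 on 40-1a replicate 2.

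Xist, expressed from the inactive X chromosome, had a signal of 3094 on cyclopamine replicate 1 and 1855 to 2351 on the other 7 arrays. The Y-linked gene Kdm5d was at 79.2 on that array and at 184.9 to 373.3 on the others, and Uty at 138.2 against 255.2 to 413.6. Eif2s3y was at 346.4 there and at 376.6 to 752.0 elsewhere.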
